A study of Mus musculus with 7 samples.

How the data were processed

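RNA was sequenced from Lgr5-positive, CD45-negative live cells that were sorted by flow cytometry from the epidermis of mouse back skin. Lgr5 marks stem cells of the hair follicle, and in these mice it was read through a green fluorescent protein. CD45 is the surface marker of leukocytes, so this gate should remove leukocytes. Per the labels, the animals were a cross of C57Bl6 and B10D2 mice, 3 samples were in Telogen, the resting phase of the hair cycle, at 45 days of age, and 4 samples were in Anagen, the growth phase, at 35 days. Per the labels' protocols, skin was depilated and trypsinised, RNA was extracted with Trizol and the libraries came from a whole-transcript amplification kit (Ovation RNA-Seq System V2). All Telogen samples were older than all Anagen samples, so age cannot be told apart from phase. No label says whether a sample is 1 mouse or a pool, so p-values measure the spread between these samples, which may be partly technical.

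The deposited table held 15415 genes with RefSeq identifiers, chromosome, start, end and length. It gave raw read counts per gene and RPKM values for the 7 samples, per the file headers. The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool and the treatment of strand and multiply mapped reads are not given in the sources used here. The lowest total over the 7 samples of a listed gene was 2 counts, and no mitochondrially encoded gene was listed. The RPKM values equalled count divided by gene length and total count within a relative tolerance of 1e-10 in 107905 of 107905 values, so they hold nothing beyond the counts, and the authors' counts were used for every test. Starts in the table were 0-based (start + 1 equalled the GENCODE M21 start for 5008 of 14906 genes of the same symbol, the start itself for 551) and are given here 1-based. GC content came from GENCODE M21 transcripts and was found for 99.4% of genes. Gapdh, a gene with many near-identical pseudogenes, had 1 to 20 counts per library, so reads of genes with close copies may have been lost and such genes are uncertain here. The same holds for genes of the H2 cluster, whose copies resemble each other.

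Total counts were 6072841, 6453337 and 5097457 in Telogen 1 to 3 and 13913148, 17042690, 15012564 and 13719893 in Anagen 1 to 4. A count of 3 corresponds to between 0.176 and 0.589 CPM in a library, where CPM are counts scaled to a common library size. The mean Anagen total was 2.54 times the mean Telogen total, and no totals overlapped, so any batch effect that goes with depth cannot be told apart from the hair cycle phase. Within groups, Spearman correlations of counts were 0.945 to 0.976, against 0.803 to 0.858 between groups. A chi-square comparison of counts gave 22.5 to 67.3 per degree of freedom within groups, so no library was a copy of another.

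The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fits) with TMM factors, after edgeR's expression filter (minimum count 10, minimum total 15), which left 12266 genes. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The model had the 2 groups and no covariate, and log2 fold changes are Anagen minus Telogen. Standard errors are the fold change divided by the square root of the F statistic. Levels are CPM of the TMM-scaled total, as mean ± SD over 3 Telogen and 4 Anagen libraries. Where a group had 0 counts, the fold is a lower bound against 3 counts over the summed library sizes of the group, and with 1 to 3 counts it is a ratio with an exact 95% binomial interval; both cover counting error only. On simulated counts for 12022 genes the test recovered 13.3% of 98 genes changed by 2-fold and 63.3% of 98 changed by 4-fold. It gave 0 wrong signs and 9 calls among 11826 unchanged genes. Far fewer genes were changed there than passed in the real data (6072). The adjusted threshold is harder to meet when few genes change, so these recovery rates do not carry over to the real test.

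The choices below were made before the data were examined. There were 28 gene lists: 15 for the stem cell state, immune genes, cell cycle, signalling and hair lineages, 10 for other cell types the sort could hold and 3 for sample quality. Lists with 3 or more tested members entered limma's camera set test (limma 3.58.1, preset correlation 0.01), camera with an estimated correlation and fry, each adjusted over 26 lists. Camera weighs a list against the other genes, while fry asks only whether the list's own genes changed. The mean log2 CPM of a list (prior count 2) was compared by an exact two-sided permutation test over the 35 splits of 7 samples, whose smallest possible p is 0.0286. Named genes were the 8 genes per direction with the largest change among those past the threshold, without overlap between groups and above the median expression, leaving out predicted genes. They were also up to 4 members of each list past the threshold with the smallest adjusted p, and last a fixed set (Lgr5, Cd34, Krt15, Nlrc5, B2m, H2-K1, H2-D1, Tap1, Tap2, Mki67, Cdkn1a, Cdkn1b, Cdkn1c and the sex-linked genes). Further list members are named where a count needs them, and some genes are counted but not reported by name here.

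The same values were recomputed with RLE size factors, library size alone, upper quartile factors, DESeq2 1.42.0, limma-voom with and without sample weights, no filter, a filter of 10 CPM in 3 samples, a replicate block, each sample left out, an adjusted p under 0.01, a fold change of 2 or more, and a fit without the 10 most abundant genes, haemoglobin genes and ribosomal RNA. Added after seeing the data were thinning of all libraries to the smallest total, leaving out Anagen 1 and Anagen 2, and offsets for GC content and gene length.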

Results

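The transcriptome of Lgr5-positive, CD45-negative hair follicle cells was measured in 3 samples from Telogen skin (45 days of age) and 4 samples from Anagen skin (35 days). Libraries held 5097457 to 6453337 counts in Telogen and 13719893 to 17042690 in Anagen. The series title concerns how quiescent stem cells meet immune surveillance, and the comparison asks how the sorted cells differ between the resting and the growing follicle. Each library pools the RNA of all its sorted cells. A change within cells therefore cannot be told apart from a change in the mix of cells, and markers of other cell types also differed (below). Levels are normalised counts in CPM (counts scaled to a common library size) ± SD, with n = 3 for Telogen and n = 4 for Anagen. Of all 12266 genes tested, 49.5% passed the test (3170 rose and 2902 fell). Counts of list members below are to be read against that share.

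Lgr5, the gene the cells were sorted on, was detected in every library and was 8.20-fold lower in Anagen. Its level was 460.2 ± 13.7 CPM in Telogen and 56.1 ± 30.6 CPM in Anagen (NM_010195, mm10 chromosome 10, 115450314 to 115587780). Markers of the quiescent bulge fell with it: Cd34, a surface marker of bulge stem cells, went from 511 ± 20.4 to 12.7 ± 5.30 CPM, and Krt15, a bulge keratin, from 8629 ± 1994 to 171 ± 65.1 CPM. Of 26 measured genes in the bulge and hair germ list, 16 fell, 7 rose and 3 did not pass the test. Krt14, a keratin of the basal layer and the outer root sheath, rose 6.85-fold. The stem cell transcription factor Sox9 (log2 fold change 1.32 ± 0.20, SE) rose too.

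The log2 fold change of Lgr5 was -3.03 ± 0.39 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000106). By the same edgeR quasi-likelihood test, Cd34 changed by -5.33 ± 0.33 (adjusted p = 1.03e-06) and Krt15 by -5.66 ± 0.33 (adjusted p = 9.35e-07). Postn and Hmcn1, which encode matrix proteins, fell 14.4-fold and 18.7-fold, Nfatc1, a transcription factor of quiescent bulge cells, fell 22.5-fold, and Fgf18, a growth factor of the resting bulge, had a log2 fold change of -7.45 ± 0.55 (SE; -8.36 without Anagen 4). As a set the list was lower in Anagen by camera (Benjamini-Hochberg adjusted p = 0.000704), and adjusted p = 0.337 with an estimated correlation. The mean log2 CPM of the list differed by -1.85 (exact permutation p = 0.0286, the smallest the design allows). The counts adjusted over the list alone were also 16 and 7; 4 members rose when a fold change of 2 or more was required, and 3 rose with offsets for GC content and length. Without Anagen 1 and Anagen 2, whose collagen genes were high, 16 members fell and 5 rose.

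**Figure D1:**
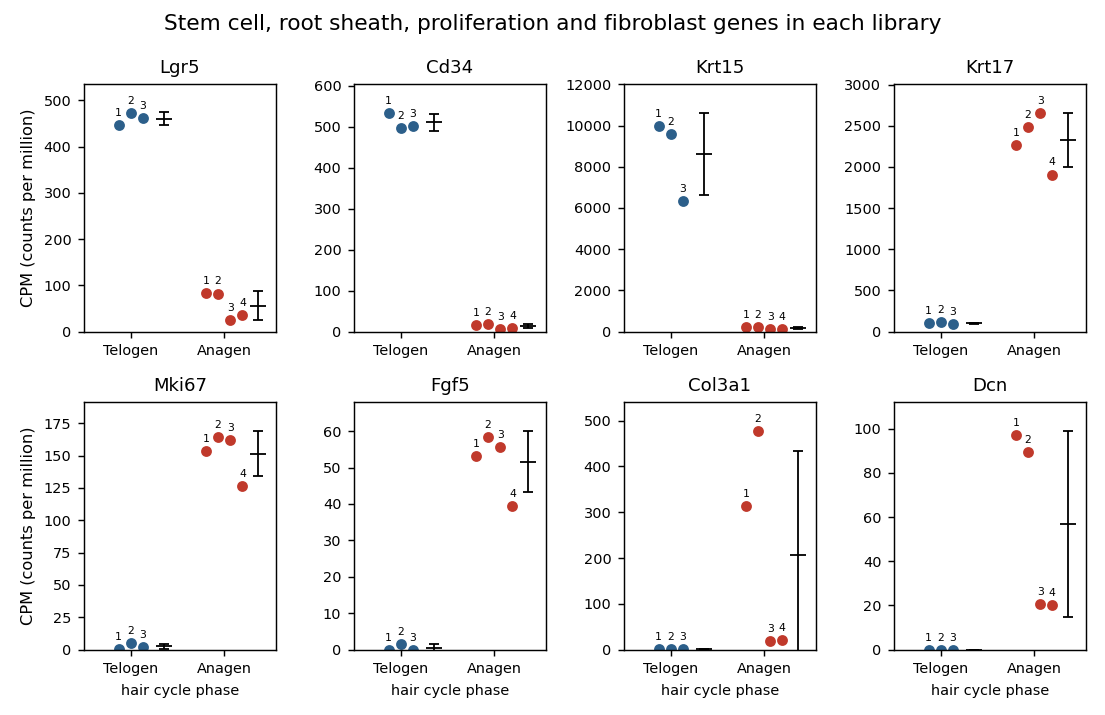
Levels in CPM (linear axes) of 8 genes in each library, numbered by replicate, with the mean and SD of 3 Telogen and 4 Anagen libraries as bars; the lower bar of Col3a1 in Anagen is clipped at 0. Lgr5, Cd34 and Krt15 lie lower in each Anagen library than in any Telogen library, and Col3a1 and Dcn lie higher in Anagen 1 and 2 than in Anagen 3 and 4.

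Of 22 measured genes of MHC class I presentation, which displays peptides to CD8 T cells, 9 rose in Anagen, 3 fell and 10 did not pass the test. The share of members that passed was close to the 49.5% of all genes tested, so the count alone does not set this list apart. Nlrc5, the transactivator of MHC class I genes, rose 78.0-fold, from 0.748 ± 0.307 to 60.2 ± 9.41 CPM (NM_001033207, mm10 chromosome 8, 94472763 to 94527272). The heavy chain genes H2-K1 and H2-D1 rose 6.02-fold (28.4 ± 3.46 to 171 ± 26.8 CPM) and 2.89-fold (84.6 ± 8.28 to 245 ± 21.8 CPM). B2m, the light chain, rose 2.80-fold, from 474 ± 66.7 to 1326 ± 165 CPM, and the peptide transporter genes Tap1 and Tap2 rose 4.36-fold and 2.56-fold.

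The log2 fold changes by edgeR's quasi-likelihood test were 6.28 ± 0.39 for Nlrc5 (SE; Benjamini-Hochberg adjusted p = 1.09e-06), 2.59 ± 0.22 for H2-K1 (adjusted p = 7.90e-06), 1.53 ± 0.18 for H2-D1 (adjusted p = 7.07e-05) and 1.49 ± 0.18 for B2m (adjusted p = 8.85e-05). H2-K1 lies at chromosome 17, 33996012 to 34000333, H2-D1 at chromosome 17, 35263094 to 35267497 and B2m at chromosome 2, 122147687 to 122153082 of mm10. The others that rose were Tapbp and H2-Q4 (log2 fold changes 1.56 and 4.38) and Tapbpl, by a ratio of 25.0 (95% interval 6.83 to 208). Tapbpl had 2 counts in Telogen, both in Telogen 3; it was at least 11.5-fold higher without that library and the ratio was 15.8 (95% interval 4.30 to 131) without Telogen 2. Those that fell were the nonclassical H2-M3 (-2.81), the chaperone gene Pdia3 (-0.66) and the proteasome activator gene Psme1 (-0.60). The immunoproteasome genes Psmb8 (0.80 ± 0.51, SE) and Psmb9 (-0.22 ± 0.45, SE) were not past the threshold. The list as a set did not pass camera (adjusted p = 0.209, and 0.656 with an estimated correlation). It passed fry (adjusted p = 0.00837, higher), which does not weigh a list against other genes. Its mean log2 CPM was 0.91 higher (exact permutation p = 0.0286, Benjamini-Hochberg adjusted 0.0482 over the lists). Counts adjusted over the list alone were again 9 and 3. Without Anagen 1 and Anagen 2, 6 members rose, Tap2, Tapbp and Tapbpl no longer passing edgeR's quasi-likelihood test (adjusted p = 0.0573, 0.0799 and 0.0777), and 1 fell. With offsets for GC content and length 7 rose, Tap2 (0.79 ± 0.30, SE) and Tapbp (0.93 ± 0.35, SE) no longer passing edgeR's quasi-likelihood test (adjusted p = 0.0508 and 0.0532). Pdia3 lost its call without Telogen 1 or any one Anagen library and Psme1 without Telogen 1, Telogen 2 or Anagen 1, 2 or 3, so that 1 member fell without Telogen 1 and without Anagen 1, 2 or 3.

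**Figure D2:**
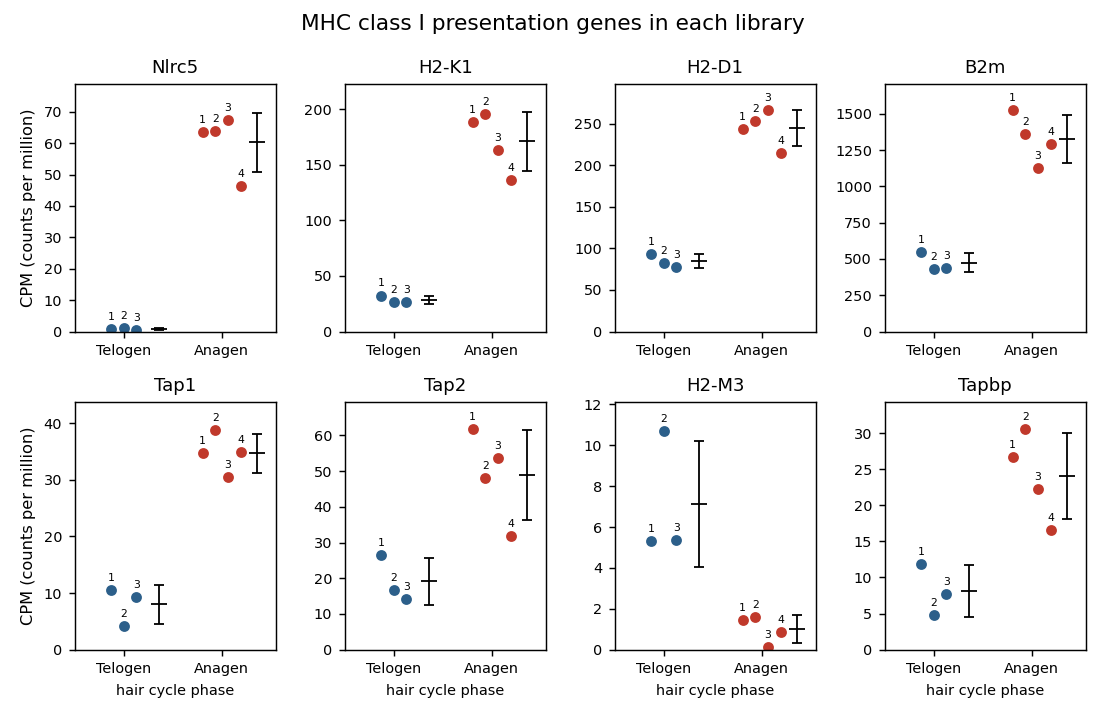
Levels in CPM (linear axes) of 8 MHC class I presentation genes in each library, numbered by replicate, with mean and SD bars of 3 Telogen and 4 Anagen libraries. Each Anagen library lies above each Telogen library in all panels but H2-M3, where each lies below.

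Interferon response genes also rose in part: of 17 measured, 9 rose and 0 fell by edgeR (1 fell at an unadjusted p under 0.05 and 1 by DESeq2, and 2 fell without Telogen 2). Without Anagen 1 and Anagen 2, 5 of 15 rose and 1 fell, and 1 fell with offsets for GC content and length. Irf9, a transcription factor of interferon signalling, rose 9.26-fold (14.3-fold without Telogen 3). The share of members past the threshold was near the 49.5% of all genes tested. The list did not pass camera (adjusted p = 0.325, and 0.634 with an estimated correlation) but passed fry (adjusted p = 0.0207, higher). Of 16 genes for immune evasion and ligands of natural killer cells, 7 fell and 3 rose; Nt5e, which makes adenosine outside the cell, fell 11.6-fold, H60c, a ligand of the receptor NKG2D, fell 18.1-fold, Fas fell 36.9-fold (78.9-fold without Anagen 2), and Vtcn1 rose 15.6-fold. That list had a camera adjusted p of 0.115 (0.337 with an estimated correlation) and a fry adjusted p of 0.00135, lower. Only 1 of its members rose when Telogen 1, Telogen 2, Anagen 1, Anagen 4 or both Anagen 1 and 2 were left out, and with the offsets. In the MHC class II list, 3 genes were measured, of which H2-DMb1 fell (at least 53.7-fold lower, with 0 counts in Anagen), and the set had a camera adjusted p of 0.761. Counts adjusted over the list alone differed only for MHC class II, where 1 rose and 1 fell, as also without Telogen 2 and with the offsets. Of 3 measured leukocyte markers, 1 fell (Cd3g, 0 counts in Anagen, at least 167-fold lower, or at least 78.0-fold without Telogen 3) and 0 rose by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.761). Cd3g was too low to be tested without any one Anagen library, 2 markers fell without Telogen 1 or Telogen 2, and 1 rose without Telogen 3 and with the offsets. In all, 15 leukocyte markers summed to 5.56 to 11.8 CPM per Anagen library and 7.47 to 50.5 CPM per Telogen library.

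Mitosis genes were higher in Anagen almost throughout: of 30 measured, 29 rose and 1, the cyclin gene Ccna2, fell (log2 fold change -1.30 ± 0.22, SE). Mki67, a marker of cycling cells, rose 59.4-fold, from 2.49 ± 2.25 to 152 ± 17.4 CPM, and 123-fold without Telogen 2, which held most of its Telogen reads. Cenpf, a kinetochore gene, had 0 counts in Telogen and was at least 154-fold higher, and Ccnb2, a mitotic cyclin, had a ratio of 159.6 (95% interval 44.1 to 1319.6), or was at least 65.4-fold higher without Telogen 2, which alone in Telogen had reads. By contrast, of 27 DNA replication genes 2 rose (Mcm2 and Tk1) and 7 fell, among them Dut (5.97-fold), which removes dUTP, and the primase and polymerase genes Prim1 (2.72-fold) and Pola1 (3.65-fold). Of 18 cell cycle inhibitors and quiescence genes, 7 rose and 6 fell; Cdkn1a rose 2.48-fold, Foxo1 7.29-fold, and Cdkn1b did not pass edgeR's quasi-likelihood test (-0.42 ± 0.20, SE; Benjamini-Hochberg adjusted p = 0.108).

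The log2 fold change of Mki67 was 5.89 ± 0.52 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.03e-06). Camera gave an adjusted p of 2.69e-06 for the mitosis list, and adjusted p = 0.318 with an estimated correlation; it gave 0.761 for DNA replication, whose median log2 fold change (0.42) and mean (0.18) were above 0 while camera's direction was lower, and 0.761 for the inhibitors. The mean log2 CPM of the mitosis list differed by 3.99 (exact permutation p = 0.0286) and that of the replication list by 0.23 (exact permutation p = 0.371). Adjusted over the list alone, 6 replication genes fell and the other counts were unchanged. Without Telogen 2, 4 replication genes rose and 4 fell, and without Anagen 4, 4 rose. Without Anagen 1 and Anagen 2, 22 of 28 tested mitosis genes rose and 1 fell, 0 of 25 replication genes rose by edgeR (1 at an unadjusted p under 0.05), and 3 inhibitors fell; with offsets for GC content and length 1 replication gene rose. Cdkn1c had a log2 fold change of -1.97 ± 0.69 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0358) and lost that call without Telogen 1 or 2 or without Anagen 1, 2 or 3, while Cdkn1b passed without Anagen 4.

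In the companion and outer root sheath list, 11 of 12 measured genes rose in Anagen and Lmo1 fell: Krt17 rose 22.9-fold, from 102 ± 7.37 to 2330.3 ± 325 CPM, Krt6a 7.94-fold and Fgf5, a growth factor that ends Anagen, 88.1-fold (at least 184-fold without Telogen 2, which alone in Telogen had reads). In the hair matrix and shaft list, 10 of 18 rose and 3 fell; Ovol1 had a log2 fold change of 3.32 ± 0.34 (SE), Hoxc13 rose 2.95-fold and the inner root sheath keratin gene Krt25 by a ratio of 148 (95% interval 41.0 to 1226), while Gata3 fell 3.48-fold. Krt25 was at least 64.8-fold higher without Telogen 1 and had a ratio of 93.5 (95% interval 25.8 to 773) without Telogen 2. Differentiation genes of the epidermis between follicles went the other way, with 9 of 13 lower and 2 higher: Krt10 fell 36.9-fold, Krt1 by a ratio of 1560.2 (95% interval 431 to 12904) and Krt77 by a ratio of 691 (95% interval 235 to 3361), while Dsg1a rose 5.94-fold. Krt1 was at least 799-fold lower without Anagen 1 and Krt77 at least 542-fold lower without Anagen 4, in each case the only Anagen library with reads. Of 7 sebaceous gland genes 3 rose (Mgst1, Plin2 and Far2) and 1, Dgat2, fell.

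Krt17 had a log2 fold change of 4.52 ± 0.21 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.84e-07) and Krt10 one of -5.21 ± 0.29 (adjusted p = 6.11e-07, the same edgeR test). Camera adjusted p-values were 0.000704 for the companion and outer root sheath list (adjusted p = 0.318 with an estimated correlation), 0.209 for the matrix and shaft list, 0.0147 for epidermal differentiation (adjusted p = 0.337 with an estimated correlation) and 0.761 for the sebaceous list. Adjusted over the list alone, 11 matrix and shaft genes rose, and 10 epidermal genes fell and 3 rose. Without Anagen 1 and Anagen 2, 9 of 10 tested companion and outer root sheath genes rose and 1 fell, and 6 of 16 matrix and shaft genes rose and 2 fell. Far2 lost its call without Telogen 3 or without Anagen 1, 2 or 3, and 3 sebaceous genes fell without Telogen 1 and 2 without Anagen 1 and Anagen 2 or with offsets for GC content and length.

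**Figure D3:**
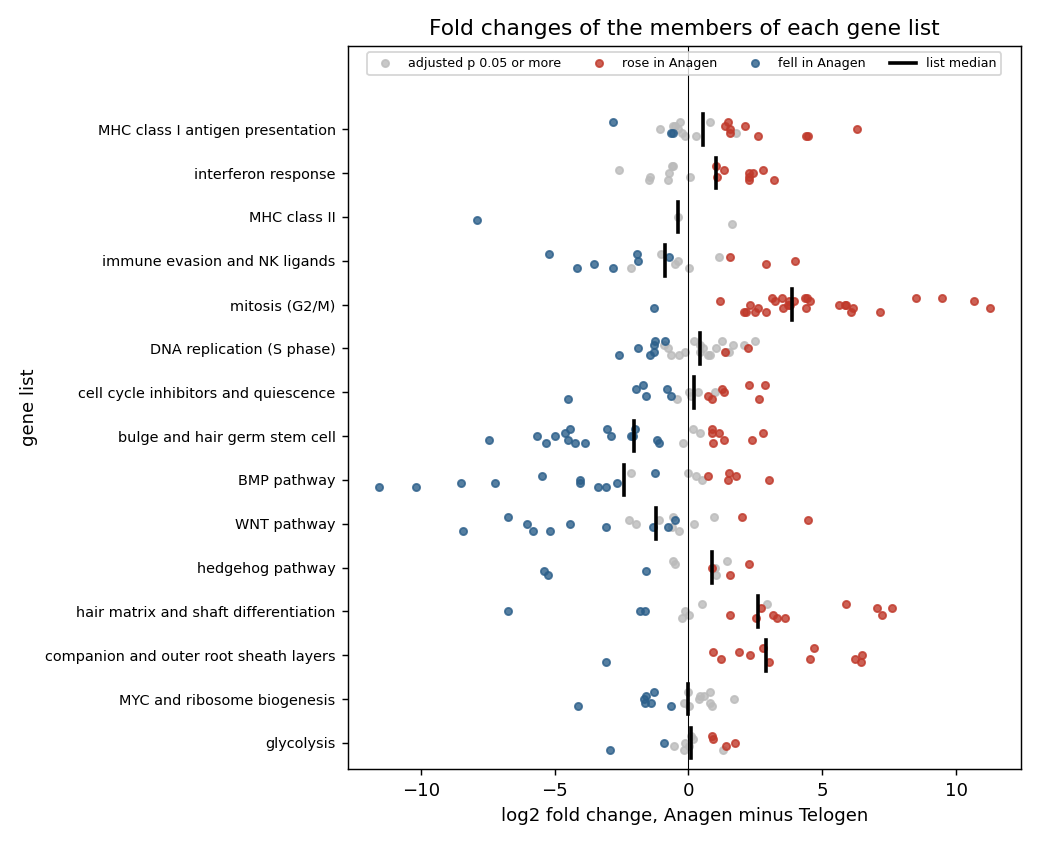
Log2 fold change (Anagen minus Telogen) of each tested member of 15 gene lists, coloured by whether the gene rose, fell or did not pass an adjusted p of 0.05, with each list's median as a bar. Of 30 mitosis genes 29 lie in the group that rose, and of 26 bulge and hair germ genes 16 lie in the group that fell.

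Of 20 BMP pathway genes, 11 fell in Anagen and 5 rose; the BMP antagonists Nog and Grem1 fell 3018-fold and 1168-fold, the ligand Bmp2 151-fold and the target gene Id2 16.7-fold. Of 20 WNT pathway genes, 10 fell and 2 rose: Wif1 and Dkk3, which encode inhibitors or inhibitor-like proteins, fell 339-fold and 21.4-fold, the ligand Wnt4 8.39-fold, the target genes Axin2 and Lef1 had log2 fold changes of -6.02 (-5.37 without Telogen 2, -6.86 without Anagen 3) and -6.74 (-5.97 without Telogen 2), and Ccnd1 rose 3.95-fold. Of 11 hedgehog genes, 3 rose and 3 fell; Ptch1 rose 4.78-fold, and Cdon and Boc, co-receptors, and Hhip fell 38.2-, 2.97- and 41.9-fold. Without Anagen 1 Wif1 fell 767-fold, and without Anagen 2 Hhip fell 124-fold and Lef1, then at 0 counts in Anagen, at least 183-fold. In the MYC and ribosome biogenesis list, 7 of 17 fell and 0 rose by edgeR (2 at an unadjusted p under 0.05, 0 by DESeq2, 2 without Telogen 3); Odc1 fell 17.6-fold and Ncl 2.66-fold. In glycolysis, 4 of 13 rose and 2 fell; Pfkp rose 2.63-fold and Hk1 fell 7.62-fold, and 1 gene fell when any single library but Telogen 1 was left out.

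Nog had a log2 fold change of -11.56 ± 0.45 and Id2 one of -4.06 ± 0.21 (SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.06e-07 and 3.71e-07). The ratio of Nog was 4970.1 (95% interval 1375 to 41055) without Anagen 2 and 5446 (95% interval 1507 to 44985) without Anagen 4. Camera adjusted p-values were 0.0155 for BMP and 0.0147 for WNT (adjusted p = 0.318 and 0.337 with an estimated correlation), 0.761 for hedgehog, 0.209 for MYC and 0.761 for glycolysis. The hedgehog list had a median log2 fold change of 0.88 and a mean of -0.47, and with offsets for GC content and length 1 of its genes rose and 5 fell. Without Anagen 1 and Anagen 2, 2 of 12 tested glycolysis genes rose and 1 fell. Adjusted over the list alone, 12 BMP genes fell and 1 glycolysis gene fell.

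Over all 12266 genes tested, 3170 rose and 2902 fell in Anagen, 49.5% of the total. A fold change of 2 or more was seen in 2668 that rose and 2398 that fell. The groups did not overlap in 54.6% of genes, against 5.71% by chance. Among the largest increases were 7 genes with 0 counts in Telogen: Lrat, which esterifies retinol (at least 541-fold higher), S100b (at least 383-fold), Grik3 (at least 325-fold), Dcn (at least 321-fold), Car6 (at least 262-fold), Nes (at least 247-fold) and Slc7a11, a cystine transporter (at least 203-fold). Every lower bound against 0 counts in Telogen in this text for a gene that rose is 1.59 times smaller without Telogen 2, which leaves fewer reads to set it. Cmah, with 1014 ± 197 CPM in Anagen and 0.345 ± 0.322 in Telogen, had a log2 fold change of 11.44 ± 0.48 (SE) and a ratio of 5386 (95% interval 1491 to 44476) without Telogen 2. The largest decreases were Serpinb10 (1202 ± 269 CPM in Telogen, 0.134 ± 0.143 in Anagen), Krt24 (1898 ± 262 and 0.427 ± 0.290 CPM), Nog, Mme (1477-fold lower), S100a4 (1349-fold lower) and 3 genes with 1 or 2 counts in Anagen: Akr1c14, ratio 3995 (95% interval 1105 to 33009), Cck, ratio 3098 (95% interval 555 to 122530.0), and Stfa3, ratio 2424 (95% interval 669.7 to 20036). Without the only Anagen library with reads, Akr1c14 was at least 1847-fold lower (without Anagen 2), Cck at least 795-fold (without Anagen 1) and Stfa3 at least 1106-fold (without Anagen 2). The biological coefficient of variation was 38.8%.

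**Figure D4:**
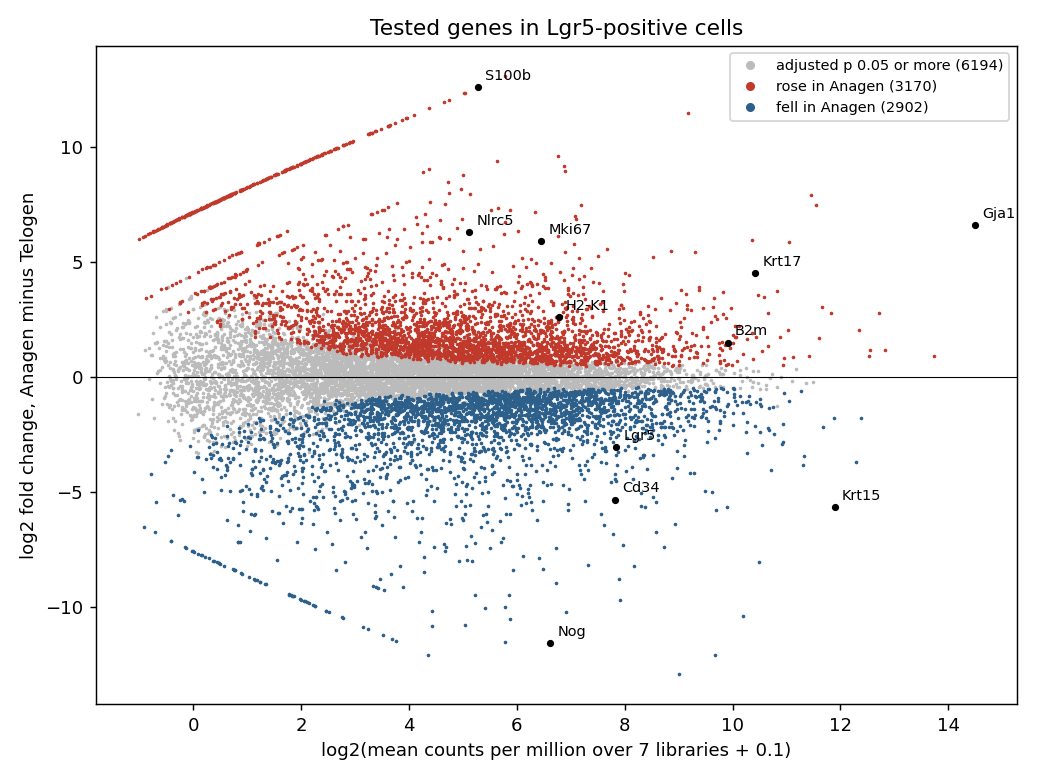
Log2 fold change (Anagen minus Telogen) of the 12266 tested genes against the log2 of the mean CPM over 7 libraries plus 0.1; red points rose, blue points fell and grey points did not pass an adjusted p of 0.05. The straight diagonal rows are genes with 0 or few counts in a group, whose fitted fold change depends on the prior count. Of the genes tested, 3170 rose and 2902 fell.

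Markers of other cell types moved unevenly. Of 15 fibroblast and dermal papilla genes, 9 rose and 3 fell, and their levels differed between Anagen libraries: Col3a1 was 313, 476, 19.05 and 20.4 CPM in Anagen 1 to 4 and 0.356, 0.319 and 0.594 CPM in Telogen 1 to 3, and Dcn was 97.0, 89.4, 20.6 and 20.3 CPM in Anagen and 0 in Telogen. Vcan rose by a ratio of 102 (95% interval 28.03 to 841) and Crabp1, a dermal papilla gene, fell by a ratio of 251 (95% interval 43.6 to 10053). Vcan was at least 41.9-fold higher without Telogen 2, and Crabp1 at least 62.3-fold lower without Anagen 1, with a ratio of 138 (95% interval 22.6 to 5695) without Telogen 2. Col3a1 passed edgeR's quasi-likelihood test (8.93 ± 1.60, SE; Benjamini-Hochberg adjusted p = 0.00125; 8.09 without Anagen 2) but neither limma-voom test, and 5 of 11 tested fibroblast genes rose and 3 fell without Anagen 1 and Anagen 2. Of 4 endothelium and pericyte genes 2 rose (Notch3, 34.2-fold, and Cdh5, at least 24.3-fold) and Cspg4 fell 11.6-fold. Of 4 muscle genes 3 rose (Myh4, at least 51.1-fold, Acta2, 41.4-fold or 26.9-fold without Telogen 2, and Tagln, whose call was lost without Anagen 1 and Anagen 2). Of 5 melanocyte genes Mitf fell 26.2-fold and Pmel rose 2.30-fold, the latter call being lost without Telogen 1, Telogen 3, Anagen 3 or Anagen 4, without Anagen 1 and 2 together and with offsets for GC content and length; 2 fell without Anagen 3. Of 6 Schwann cell genes 2 rose, among them S100b, and Pmp22 and Mbp fell, with a list median of -1.17 and mean of 1.13, and Mbp lost its call without Telogen 3, while 1 gene rose without Telogen 1, Telogen 2, Anagen 2, Anagen 4 or both Anagen 1 and 2. All 3 measured erythrocyte genes rose from 0 counts in Telogen (Alas2, at least 31.4-fold, Slc4a1, at least 13.2-fold, and Hbb-bs, at least 8.09-fold), and only 1 of them was high enough to be tested, and rose, without Anagen 2, without Anagen 3 or without Anagen 1 and 2. The single measured adipocyte gene, Plin4, fell 4.92-fold, a call lost without Anagen 3, without Anagen 1 and 2 together or without any one Telogen library. Camera adjusted p-values for these lists were 0.604 for fibroblasts, 0.725 for endothelium, 0.209 for muscle, 0.320 for melanocytes, 0.761 for Schwann cells and 0.142 for erythrocytes.

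In the dissociation stress and immediate early list, which reports on handling of the tissue, 11 of 19 genes fell in Anagen and 0 rose by edgeR, at an unadjusted p under 0.05 or by DESeq2 (camera adjusted p = 0.00317; 0.634 with an estimated correlation). Hspa8 fell 3.38-fold, Junb 3.21-fold, Dusp1 4.54-fold and Nr4a1 4.39-fold (2.47-fold and 2.55-fold without Telogen 3). Fos, which did not pass the test, was 1611, 1278 and 5293 CPM in Telogen 1 to 3 and 1988, 1317, 527 and 647 CPM in Anagen 1 to 4. Without Telogen 3, 6 genes fell, and without Anagen 3, 7. Adjusted over the list alone, 12 genes fell. Y-linked genes were detected in all 7 libraries (Ddx3y 301 ± 8.93 CPM in Telogen and 154 ± 3.92 in Anagen; Eif2s3y 186 ± 40.9 and 109.9 ± 17.6; Uty 100.4 ± 23.9 and 90.0 ± 10.3; Kdm5d 145 ± 85.1 and 207 ± 43.9), of which Ddx3y and Eif2s3y fell, Eif2s3y losing its call without Telogen 1, without Anagen 1 and 2 together and with offsets for GC content and length. Xist, transcribed from the inactive X chromosome, was 8.78, 13.2, 3.99 and 0 CPM in Anagen 1 to 4 and 0 in Telogen, so Anagen 1, 2 and 3 held reads of both sexes' marker genes. Of the 13 mitochondrially encoded genes, none was listed, so that list was not tested.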

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

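The tests of the MHC class I pattern were chosen after the result was seen; the counts of splits were planned before their result was seen. Of 141 sets of 4 Anagen values (named genes, list means and total counts, log2 scale), 18 had a library whose gap to the nearest of the others exceeded Dixon's 95% critical value as a share of the range, where chance alone gives about 7.05, and the sets are not independent. Anagen 4 was the distant library in 9 of the 18. It was lower than the others in Nlrc5 (0.843 of the range), Ovol1 (0.867), Acta2 (0.926), Hspa8 (0.863) and the mean of the companion and outer root sheath list (0.839), and higher in Postn (0.836), Hmcn1 (0.876) and the mean of the MYC and ribosome biogenesis list (0.871). Hoxc13 was higher in Anagen 3 (0.871), Dgat2 higher in Anagen 2 (0.864), and the hedgehog list mean lower in Anagen 1 (0.833). Krt24 had 0 counts in Anagen 1 against 8 to 10 in the others (0.889). For Akr1c14, Cck, Stfa3, Krt1, Krt77 and Crabp1 the ratio was 1 because only 1 Anagen library had any read.

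The rise of 9 MHC class I list members in Anagen was weighed against 3 technical explanations. Leukocytes in the sort, which CD45 gating should remove, would bring their own abundant transcripts, but 15 leukocyte markers together reached at most 11.8 CPM in an Anagen library, while Nlrc5 alone was 46.4 to 67.3 CPM there. A different H2 haplotype between groups, which read mapping could favour, cannot account for the 3 list members outside the H2 region that rose (Nlrc5, B2m and Tapbpl, of which Tapbpl lost its call without Anagen 1 and Anagen 2), but it stays open for H2-K1, H2-D1, H2-Q4, Tap1, Tap2 and Tapbp. In a 5 Mb window around the H2 genes of chromosome 17, 37.3% of 102 other genes rose, against 25.7% of 12142 genes elsewhere (Fisher's exact test, two-sided p = 0.0119). That test treats neighbouring genes as independent. Only list members were left out of the 102, so genes regulated together with the list would also raise the share. The share therefore does not tell a haplotype difference from shared regulation. The shared strain label does not count against a haplotype difference. It names a cross of strains that differ in H2 haplotype and gives no generation. Depth alone is argued against by thinning to the smallest total. Nlrc5 then had a log2 fold change of 6.05, against 6.28, and 9 members rose and 3 fell. A library batch, which no label names, cannot be told apart from the phase where it goes with these totals. The smallest total in Anagen was 2.13 times the largest in Telogen. The hair cycle phase remains open as the biological explanation, but age (45 days in Telogen, 35 in Anagen) goes with it in every sample. Xist had reads only in Anagen 1, 2 and 3, so the sex make-up of the samples may differ as well. Neither age nor sex was weighed here, nor was the mix of sorted cells other than leukocytes.

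Over the 35 splits of the 7 samples into 4 and 3, only the real split, 1 of 35, gave 6072 genes past the threshold of edgeR's quasi-likelihood test; the highest of the others gave 0 (3195 at an unadjusted p under 0.05, against 6859 in the real split). The 12 MHC class I members and the 23 bulge and hair germ members past the threshold were likewise reached by 1 of 35 splits, with 0 as the highest other, which follows from the 0 genes and adds no evidence of its own. For the count of genes this is the smallest share that 35 splits can give, which argues against chance but cannot exclude it. Splits that mix the groups also raise the spread within each, which makes calls there unlikely. Chance stays open for the 7 lists past camera's threshold, since 2 of the 35 splits gave as many. The split of the Telogen libraries plus Anagen 4 against Anagen 1, 2 and 3 gave 9.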

How the results depend on the processing

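Thinning, leaving out Anagen 1 and Anagen 2, and the GC and length offsets were chosen after seeing the data; the other alternatives were planned. Over 22 alternatives, 2042 to 3431 genes rose and 2042 to 3226 fell, the lowest at an adjusted p under 0.01, where fewer genes can pass. With GC and length offsets 2559 genes rose and 2926 fell. Of the 3170 genes that rose in the main test 2234 kept that call, and of the 2902 that fell 2343 did. The offsets gave 7 called genes the opposite call, and any other alternative 0. Without offsets, log2 fold change correlated with log2 length (Spearman 0.215) and GC content (0.172) over 12217 genes. The offsets moved the median log2 fold change of all genes by -0.15, which applies to each value under them. Of 2443 values of 113 named genes, 2374 kept direction and side of the threshold, 65 lost the call, 3 gained it and 1 reversed: Eif2s3y, 0.14 with the offsets (edgeR's quasi-likelihood test, adjusted p = 0.594). The number of MHC class I members that fell was 1, against 3, with library size alone, upper quartile factors, an adjusted p under 0.01, a fold change of 2 or more, without Anagen 1 and 2 and with the offsets, and 1 to 3 with single samples left out. Bulge and hair germ members that rose were 4, against 7, at a fold change of 2 or more and 3 with the offsets. Lists lower by camera were 3, against 5, with the filter of 10 CPM, which left 19 lists to test, and 2 at an adjusted p under 0.01. Apart from the stricter thresholds and the filter, the cause was not tested.

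With single samples left out, 2587 to 3208 genes rose and 2526 to 2802 fell, and 9 to 10 MHC class I members rose. After thinning to the smallest total, 2793 rose and 2946 fell, and 9 MHC class I members rose and 3 fell. Same-numbered samples did not deviate together over all genes (correlations 0.012, 0.037 and -0.0063). This gives no sign that the numbers pair the samples, but a pairing that touches few genes would not show. With the replicate block on numbers 1 to 3, 2386 genes rose and 2381 fell. Quantile normalization and other pseudocounts were planned for normalized values and not run, since the table holds counts, and DESeq2 has no camera value. By fry, some lists had an adjusted p under 0.05 that missed it by camera. They were MHC class I, interferon, immune evasion, MYC (0.000448, lower), hedgehog (0.0253, lower), and matrix and shaft (0.0207, higher). Melanocytes (0.000226, lower), muscle (0.0207, higher), erythrocytes (0.000963, higher) and the sex-linked list (0.0306, lower) did so too. The stress list missed it by fry (0.0756). For all other lists both tests fell on the same side. Of 1100 list counts, 949 stayed within 1.5 times and 151 moved. Thinning left 11229 genes to test, against 12266. In simulated counts with these samples 13.3% of 2-fold changes were recovered, with far fewer genes changed than in the real data, so the rate does not carry over. How much of it is due to depth was not tested.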

Other observations

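The tests on collagen genes and the scan of gene families were chosen after the result was seen; the length, GC and pseudogene tests on ribosomal protein genes were written down before theirs was seen, but the need for the bound to be met by more than the median's bootstrap interval was added after the first length result. The pseudogene test replaced an earlier one on mitochondrial ribosomal protein genes, which are not members of the pattern and of which 35 of 75 fell and 1 rose. Genes were grouped by the letters that open their symbols. Of 141 families with 10 or more tested genes, 10 passed camera (Benjamini-Hochberg adjusted p under 0.05), 8 lower and 2 higher in Anagen. Only the preset correlation of 0.01 was used for families. With an estimated correlation 0 of the gene lists above passed, so the family calls are uncertain. Family median log2 fold changes also rose with family median length (Spearman correlation 0.458). Serpinb genes, inhibitors of proteases, were lower: 9 of 12 fell and 0 rose (camera adjusted p = 5.79e-05). Serpinb7 fell 122-fold, and at least 315-fold without Anagen 4, which alone in Anagen had reads of it. Serpinb11 fell 112-fold, and 211-fold without Anagen 4. Families that hold subunits and assembly factors of respiratory complexes were lower too: 9 of 10 Ndufb genes, 10 of 13 Ndufa genes and 14 of 21 Cox genes fell, and 1 Cox gene, Cox15, rose; the 14 include Cox11 and Cox17, which take part in assembly, and the subunit genes Cox5a, Cox6a1 and Cox8a did not pass the test. Myosin genes were higher, with 10 of 14 rising and 0 falling (adjusted p = 0.00288); Myo10 rose 9.55-fold and Myo5a 7.50-fold. Slc transporter genes rose in 94 of 219 and fell in 33. With GC and length offsets the Serpinb genes gave 8 that fell, the myosins 6 that rose and 2 that fell, the Ndufb genes 5 that fell, the Ndufa genes 4 that fell and 3 that rose, the Cox genes 6 that fell and 4 that rose, and the Slc genes 82 that rose and 38 that fell.

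The most abundant transcript in Anagen was Gja1, which encodes the gap junction protein connexin 43 and was named here after its values were seen. It rose 96.5-fold, from 414 ± 98.2 to 39945 ± 3946 CPM (log2 fold change 6.59 ± 0.25, SE; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.06e-07).

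Genes named Rpl or Rps for ribosomal proteins were lower in Anagen. The set takes in like-named copies and Rps19bp1, the gene of a binding protein. Of 77 tested, 56 fell and 0 rose by edgeR (1 at an unadjusted p under 0.05, 0 by DESeq2). Their median log2 fold change was -1.64 (bootstrap 95% interval -1.75 to -1.26). The bootstrap intervals here resample genes, which are not independent, so they do not measure the spread between samples. Genes of similar length were lower as well, and the fifth of genes with the shortest transcripts had a median of -0.59 against 0.53 in the longest. The ribosomal median lay below all 1000 lists matched on length (-1.61 to -0.21, median -0.94), which met the bound set in advance, but by less than its own interval, so this test alone does not exclude length. With offsets for GC content and length the median was -0.75 (-0.90 to -0.54), 40 genes fell and 3 rose, which argues against those trends as the whole cause, although they may account for part of the fall. Genes with more annotated pseudogenes of their own name did not fall more (Spearman correlation with log2 fold change 0.238, interval 0.0186 to 0.441, across genes, which are not independent), pseudogenes under other names were not counted, and the phase remains an untested biological explanation.

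Fibroblast genes differed between the 4 Anagen libraries, Col3a1 by 25.0-fold from lowest to highest. Dermal fibroblast RNA in differing amounts would keep collagen genes in 1 ratio, and the ratio of Col1a1 to Col3a1 varied only 1.49-fold between Anagen libraries. Collagen genes that vary together within the sorted cells would keep 1 ratio too. The ratio therefore does not identify the source, and such RNA stays a candidate only. A single source with a fixed profile is argued against by Dcn, whose ratio to Col3a1 varied 5.76-fold. The Lgr5 gate would remove fibroblasts without that receptor, Col6a1 fell in Anagen (log2 fold change -4.58, or -5.37 without Anagen 1), and no biological explanation was tested.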
